A study of Bos taurus with 36 samples.

How the data were processed

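Digital dermatitis is an infectious skin disease of the bovine foot in which spirochaetes of the genus Treponema are abundant. The samples were 36 punch biopsies from the centre of lesions of Holstein cows of 10 herds. Per the labels' protocols, DNA was extracted from the biopsies and a part of the bacterial 16S rRNA gene was amplified with primers specific for Treponema. Each sample carried its own barcode, and the amplicons were pooled in equal amounts and sequenced by pyrosequencing on a Roche FLX+ Titanium instrument. Shares below are therefore shares among treponeme amplicons, not among all bacteria of a lesion. No samples of healthy skin were analysed here.

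The deposited tables give, for each lesion, clusters of similar reads. Read counts per cluster were deposited by the authors as whole numbers without normalization, per the file headers. The maximum distance within a cluster is a fraction, per the file headers, and reached 0.0297. A sum of squared distances, a score per the file headers, was also deposited and was not used here. The percent identity of a cluster's representative read to its best BLAST match was deposited for the named clusters, per the file headers, and ranged from 92 to 100. The clustering tool, the distance limit, the read trimming, the chimera removal and the BLAST database version are not given in the sources used here.

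Of 5406 clusters, 555 carried a name, and these held 56205 of 75265 reads, or 74.7%. Clusters without a name held 25.2% ± 7.61 (SD, n = 36) of a lesion's reads. Names were given mainly to larger clusters, so a taxon without a named cluster is not shown to be absent from a lesion. The smallest named cluster of a lesion held between 10 and 36 reads. A taxon with at least 1 read in a named cluster thus had at least 10 reads, a larger share in lesions with few reads. The largest cluster without a name held at most 3.39% of a lesion's reads. In 11 lesions every cluster of 12 or more reads had a name, and in the other 25 some did not. The 11 comprise all lesions of herds 2, 3, 4 and 5, lesion 1 of herd 6 and lesion 2 of herd 11, so this difference between the tables nearly coincides with herd. It was treated as a processing batch.

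The 85 spellings of names were reduced to 34 taxa. Names given together for a cluster in at least 2 tables were merged. This joined T. denticola with PT7 (named together in 5 lesions), T. medium with PT5 (in 2 lesions) and PN-20 with PT12 (in 2 lesions). T. denticola and PT7 were also named as separate clusters in 16 lesions, so that merged taxon may hold more than 1 phylotype. A name pair given in a single table counted for the name given first. This merging was chosen after the names and read counts were seen and before any test between herds or of co-occurrence. PT codes are taxa that the tables name by a code only.

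A share is the reads of a taxon's named clusters divided by all reads of the lesion, named or not. Lesions held between 286 and 7235 reads, with a median of 1957.5. Intervals for single lesions are 95% Wilson binomial intervals and cover counting error only, because PCR reads without molecular identifiers are not independent molecules. All representative read identifiers shared 1 run prefix. The most similar pair of lesions had a Bray-Curtis distance of 0.101, and no pair was counted as 1 sample.

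The tests were fixed before the data were examined. Neighbouring pairs of the 6 leading taxa were compared within lesions by a sign-flip permutation test. Herds with at least 2 lesions (35 lesions, 9 herds) were compared by permutational analysis of variance of Bray-Curtis distances, by the mean distance within against between herds, and by Kruskal-Wallis statistics with permuted herd labels. The number of taxa was taken after thinning every lesion to 286 reads, as the mean of 100 draws. All permutation tests used 100000 resamples, or 20000 when single lesions were left out, and were two-sided except the analysis of variance and the Kruskal-Wallis tests, which are one-sided by construction. The smallest p they can give is 1e-05. Correlations over fewer than 10 values used all orders of the values, so their permutation tests are exact. Taxa were tested between herds with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust=TRUE, R 4.3.3), with the lesion's total reads as library size, for 23 taxa with at least 10 reads and found in at least 3 lesions. Co-occurrence was tested by Fisher's exact test, two-sided, for taxa in 20% to 80% of lesions. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.

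Each herd was sampled on 1 date, so herd and date cannot be told apart. The labels do not say whether lesions of a herd came from different cows, so p-values measure the spread between these lesions. The text names the taxa with a mean share of at least 1% or found in at least 50% of lesions, at most 25, the 5 taxa with the lowest adjusted p of those past the herd test, and the lesions whose highest taxon lies outside the 6 leading ones. Other taxa are named where a co-occurrence test called them, or, as stated, after their values were seen.

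The edgeR test was tested on simulated data for the 23 taxa, with the real library sizes and herd sizes, in 30 data sets per setting in which 6 taxa were changed in 3 herds. With each taxon's own estimated dispersion (median 13.6) it called 26.5% of unchanged taxa when nothing was changed, so it did not hold its error rate on counts this dispersed. With 6 taxa changed it called 31.1% of those changed 8-fold and 87.8% of those changed 64-fold, beside 25.6% and 30.0% of the unchanged taxa. After this failure 2 further simulations were added. With a dispersion of 1, far below the estimate, it called 90% of taxa changed 8-fold and 100% of taxa changed 64-fold, and 0% of taxa when nothing was changed. With the real lesions shuffled between herds it called 6.52% of taxa when nothing was changed, 23.9% of taxa changed 8-fold and 60.6% of taxa changed 64-fold. An edgeR likelihood ratio test called 12.2% of unchanged taxa with the own dispersions. A permutation Kruskal-Wallis test called 0% there, and 11.1% of taxa changed 64-fold. The edgeR test was also run on the real data with robust=FALSE, with legacy=FALSE in both forms and as the likelihood ratio test, and each called 0 taxa. The design fixed beforehand was kept as the main one.

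The permutation tests were tested on simulated communities of 13 taxa with the real herd sizes, in 100 data sets per setting. With nothing changed, the analysis of variance had a p under 0.05 in 2% of data sets and the distance comparison in 3%. With taxa changed 64-fold in 3 herds these shares were 69% and 67%, and at 8-fold 22% and 19%. The Kruskal-Wallis test passed in 6% of data sets with nothing changed, in 60% at 8-fold and in 99% at 64-fold for a value above 0 in every lesion. For a value that was 0 in about 50% of lesions, the setting tried first, it passed in 7%, 9% and 6%. There the zeros fell at random over the herds and only values above 0 were changed, so it had almost no power for such changes. A difference between herds in presence was not simulated. The setting above 0 was added after that result. Fisher's test was simulated without herds, with linked pairs alike in nearly all lesions. It called 96.7% of linked pairs and 0.042% of pairs when none was linked. Neither rate covers lesions grouped in herds or weaker links.

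Alternatives fixed beforehand were averages over herds or pooled reads, other presence limits, log and square-root scales, Jaccard and centred log ratio distances, herds with at least 3 lesions, TMM scaling, DESeq2 1.42.0, a Kruskal-Wallis test, other filters, no thinning, the inverse Simpson index, permutation within herds, and leaving out each lesion in turn. Alternatives chosen after seeing the data were shares of named reads, unmerged or more widely merged names, an identity of at least 97%, the lesions of each naming batch alone (for dates and depth too), communities without T. pedis, a presence limit of 5%, permutation within naming batches, and the other edgeR fits. Clustering at another identity was not run because the tables hold no sequences.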

Results

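The treponemes of 36 digital dermatitis lesions from 10 herds of Holstein cows were surveyed by sequencing 16S rRNA amplicons, in order to describe which Treponema taxa the lesions hold. Herd 2 contributed 1 lesion, herds 5 and 9 contributed 2 each, herds 3, 4, 10 and 11 contributed 3 each, herd 8 contributed 5, herd 6 contributed 6 and herd 7 contributed 8. The herds were sampled over 183 days. The lesions held 75265 reads in all, between 286 and 7235 per lesion, and 34 taxa were named, of which 9 were named in 1 lesion only. A lesion held named clusters of 4 to 16 taxa, with a median of 9.

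T. phagedenis, a treponeme regularly cultured from these lesions, was named in 36 of 36 lesions and had the highest mean share, 14.6% ± 9.75 (SD, n = 36). T. pedis followed with 9.91% ± 17.7 (SD, n = 36) but was named in only 16 lesions. T. medium/PT5 had a mean share of 9.89% ± 12.6 (SD, n = 36) and was named in 31 lesions. T. denticola/PT7, of which T. denticola is also known from human periodontal disease, had 8.50% ± 7.27 (SD, n = 36) and was named in 32 lesions. The coded taxa PT8 and PT18 had mean shares of 6.32% ± 13.6 and 5.96% ± 10.0 (SD, n = 36) and were named in 14 and 15 lesions. These 6 leading taxa together made up 55.2% ± 17.2 (SD, n = 36) of a lesion's reads.

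The leading taxa fell into 2 kinds of distribution. T. phagedenis, T. medium/PT5 and T. denticola/PT7 were named in most lesions, whereas T. pedis, PT8 and PT18 were missing among the named clusters of most lesions and abundant in some. Where T. pedis was named its mean share was 22.3% ± 20.9 (SD, n = 16), where PT8 was named it was 16.3% ± 17.9 (SD, n = 14), and where PT18 was named it was 14.3% ± 11.2 (SD, n = 15). T. pedis reached 64.4% of the reads of herd 4 lesion 3 (95% Wilson interval 61.7% to 67.0%, 823 of 1278 reads). T. medium/PT5 reached 53.5% in herd 11 lesion 2 (47.7% to 59.2%), the lesion with the fewest reads, and PT8 reached 48.6% in herd 9 lesion 1 (46.5% to 50.8%). T. phagedenis ranged from 0.708% in herd 3 lesion 3 (0.385% to 1.30%) to 43.8% in herd 6 lesion 1 (41.7% to 46.0%).

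**Figure D1:**
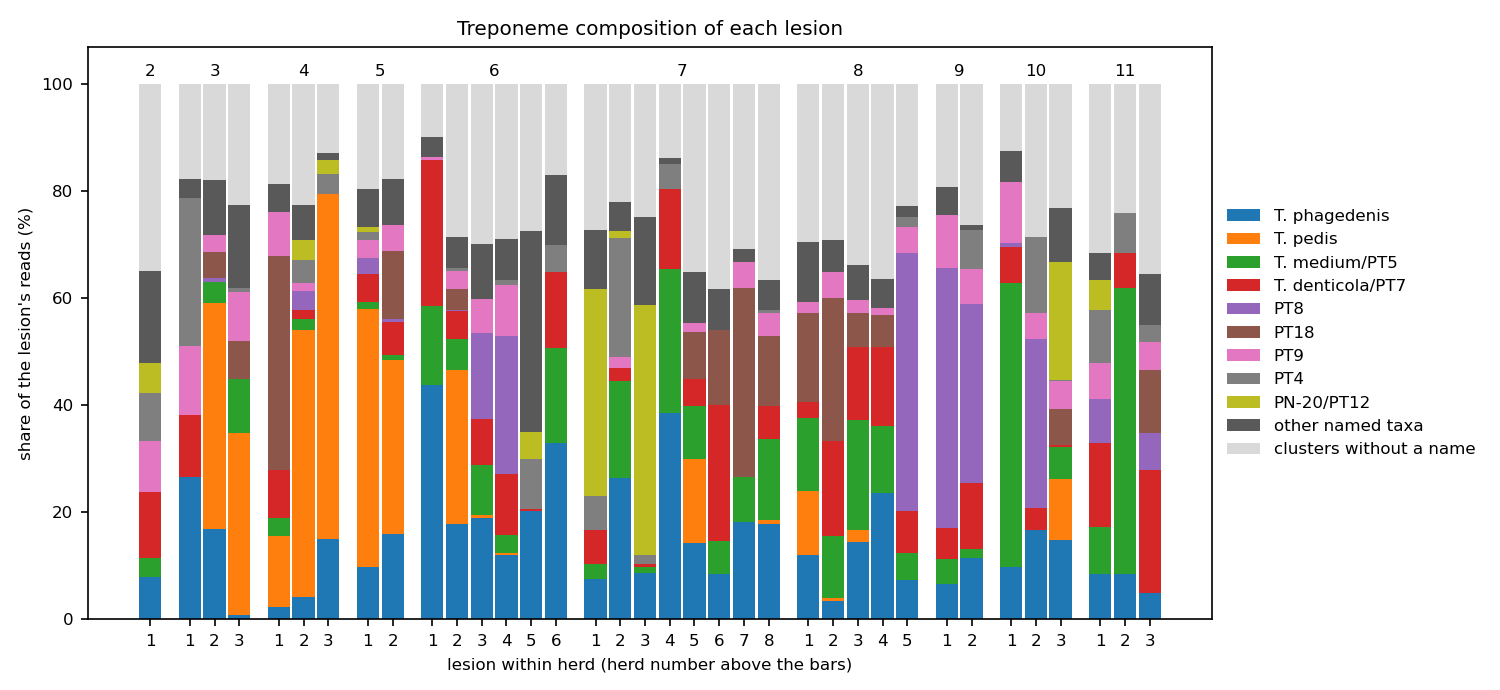
Each bar is 1 lesion, grouped by herd, and its coloured parts are the shares of the lesion's reads in percent held by the 9 taxa with the highest mean share, by other named taxa and by clusters without a name. T. phagedenis is present in all 36 bars, and T. pedis in 16.

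Below the leading taxa, PT9 was widespread at low shares, with 4.19% ± 3.66 (SD, n = 36) in 28 lesions. PT4 had 3.96% ± 6.37 (SD, n = 36) in 22 lesions. PN-20/PT12 had 3.67% ± 10.4 (SD, n = 36) and was named in 10 lesions. The mean shares of oral taxon 517 and PT15 were 1.24% ± 1.97 and 1.13% ± 5.61 (SD, n = 36), in 14 and 8 lesions. The clone 18f-22 had 0.894% ± 1.23 (SD, n = 36) in 18 lesions. The mean share of PT15 rested on herd 6 lesion 5, without which it was 0.200%, and that of PN-20/PT12 was 2.44% without herd 7 lesion 3.

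In 5 lesions a taxon outside the leading 6 had the highest share. PN-20/PT12 led herd 7 lesion 1 with 38.8% (37.4% to 40.2%), herd 7 lesion 3 with 46.8% (44.6% to 49.0%) and herd 10 lesion 3 with 21.9% (20.7% to 23.1%). PT15 led herd 6 lesion 5 with 33.7% (32.01% to 35.42%). PT4 led herd 3 lesion 1 with 27.8% (24.9% to 30.9%).

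T. phagedenis exceeded T. pedis in 26 of 36 lesions, but the mean difference of 4.71 percentage points ± 21.8 (SD, n = 36) did not pass the sign-flip permutation test (p = 0.204, adjusted p = 0.939). None of the 5 neighbouring pairs of leading taxa passed it, so the order of their mean shares was within the spread between lesions. On the scale of log2(percent + 0.1) 3 of the 5 pairs passed. There T. phagedenis lay above T. pedis by 3.95 (adjusted p = 5e-05), T. pedis lay below T. medium/PT5 with a difference of -2.41 (adjusted p = 0.0064), and T. denticola/PT7 lay above PT8 by 3.08 (adjusted p = 5e-05). A lesion without a named cluster of a taxon enters this scale at 0.1%. T. pedis was named in 16 lesions and PT8 in 14, so these differences reflect how often a taxon was named as well as its share. T. medium/PT5 was the higher of its pair with T. pedis in 22 lesions and the lower in 10. In 5 comparisons added after the data were seen, the same test was applied to mean differences in share between T. phagedenis and each other leading taxon. T. phagedenis was picked for its highest mean share, which favours it. It lay above T. denticola/PT7 by 6.13 percentage points (adjusted p = 0.00547), PT8 by 8.30 (adjusted p = 0.0169) and PT18 by 8.66 (adjusted p = 0.00547). It was higher in 28, 30 and 29 of 36 lesions. The mean differences from T. medium/PT5 (4.73, higher in 28 lesions) and T. pedis (4.71, higher in 26) did not pass (adjusted p = 0.0757 and 0.204). All these tests take lesions of a herd as independent. With 1 value per herd, 0 of the 5 neighbouring pairs passed, and the comparisons added for T. phagedenis were not repeated that way.

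Herds were compared to ask whether lesions of a herd share a treponeme community. T. pedis had the widest range of herd means but passed no test between herds after adjustment in the main fit (edgeR quasi-likelihood F test, adjusted p = 0.329) or by Kruskal-Wallis permutation (adjusted p = 0.141). Its mean shares were 25.4% ± 22.4 (SD, n = 3) in herd 3, 42.5% ± 26.4 (SD, n = 3) in herd 4 and 40.3% ± 11.2 (SD, n = 2) in herd 5. Its mean was 4.96% ± 11.7 (SD, n = 6) in herd 6, 2.04% ± 5.50 (SD, n = 8) in herd 7, 2.97% ± 5.16 (SD, n = 5) in herd 8 and 3.82% ± 6.62 (SD, n = 3) in herd 10, and no cluster was named T. pedis in herds 2, 9 and 11. Each of these 4 means rested mainly on 1 lesion, with 28.8% in herd 6, 15.6% in herd 7, 12.1% in herd 8 and 11.5% in herd 10. PT8 averaged 41.1% ± 10.7 (SD, n = 2) in herd 9 and was named in none of the 8 lesions of herd 7. T. phagedenis had its highest herd mean in herd 6, 24.3% ± 11.8 (SD, n = 6).

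**Figure D2:**
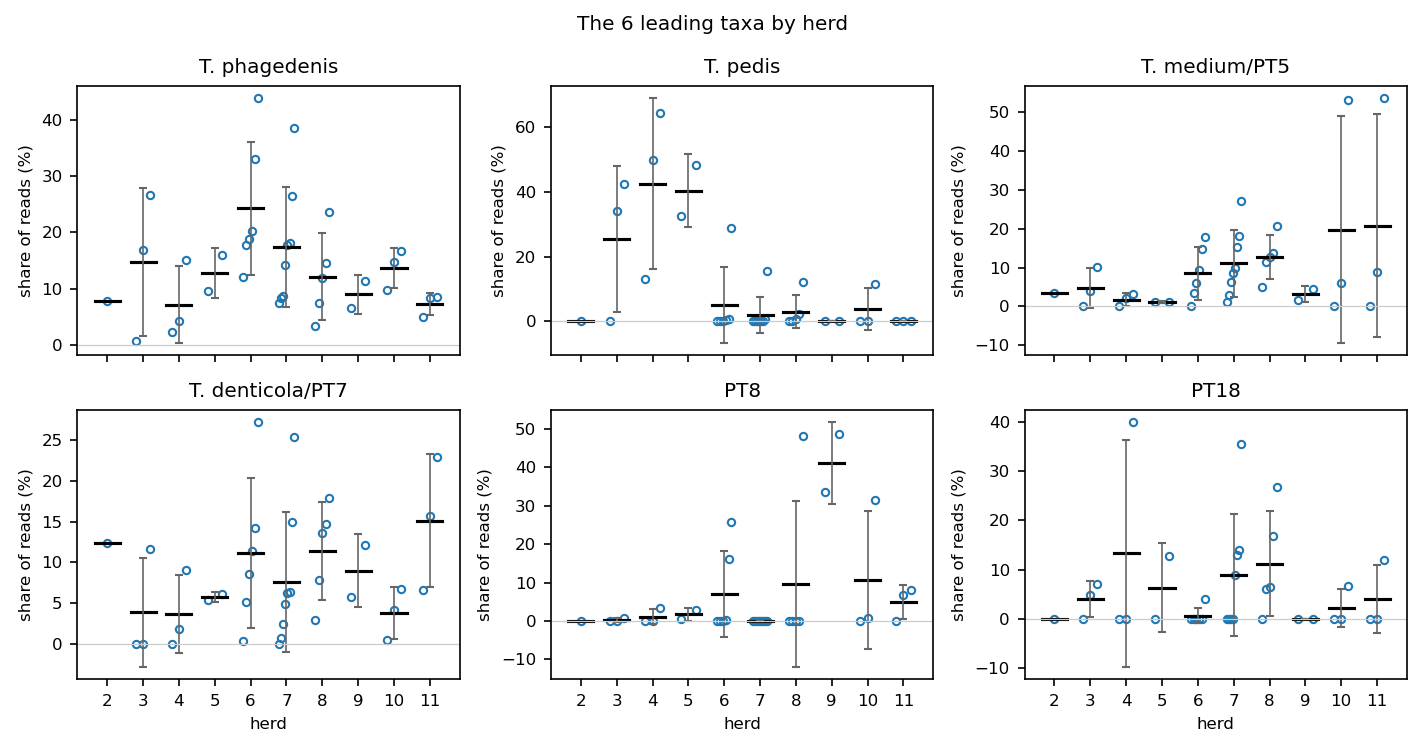
Each panel shows 1 of the 6 leading taxa, with the share of reads in percent on the vertical axis and the herd on the horizontal axis. Circles are lesions, thick lines herd means and thin bars ± 1 SD. T. pedis has herd means of 25.4% to 42.5% in herds 3, 4 and 5 and at most 4.96% elsewhere.

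Herd accounted for 0.339 of the sum of squared Bray-Curtis distances (35 lesions, 9 herds, permutation p = 0.00774). Random groups also give a share above 0, so 0.339 overstates the part linked to herd. The share depends on the numbers of herds and lesions, so shares from different sets of lesions cannot be compared in size. Among herds with at least 3 lesions the share did not pass (0.263, 31 lesions, 7 herds, permutation p = 0.0547). Lesions of the same herd were closer to each other than lesions of different herds, with mean distances of 0.598 and 0.647 and a difference of -0.0494 (permutation p = 0.0347), but leaving out any 1 of 14 of the 35 lesions lost this call (p up to 0.0899). Neither difference passed within either naming batch. Among the 8 lesions of herds 3, 4 and 5 the herd share was 0.137 (permutation p = 0.957) and the distance difference 0.0837 (permutation p = 0.139), and among the 25 lesions with fewer named clusters these were 0.254 (permutation p = 0.145) and -0.00987 (permutation p = 0.724). Without T. pedis the herd share was 0.277 (permutation p = 0.125), and distances that give less weight to abundant taxa did not pass either, with p = 0.0767 for square roots of shares in a permutation test.

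Of 23 taxa, edgeR's quasi-likelihood F test called 0 between herds. PT8 had the lowest adjusted p, 0.0845, and 6 taxa had an unadjusted p under 0.05, namely PT8, PT13, PT15, oral taxon 237, PN-20/PT12 and oral taxon 258. DESeq2 called 0 taxa with 0 at an unadjusted p under 0.05 among the 17 for which it gave a p, and it gave none for 6, among them PT13, PT15 and oral taxon 237. The permutation Kruskal-Wallis test called 0 with 2, T. pedis (p = 0.00612, adjusted p = 0.141) and PT8 (p = 0.0458, adjusted p = 0.440). Without a filter on low counts edgeR called 5 taxa, T. pedis, PT8, PN-20/PT12, PT13 and canine oral taxon 198. PT8 passed without herd 4 lesion 2 (adjusted p = 0.0210), without herd 6 lesion 5 (adjusted p = 0.0382) and without herd 8 lesion 5 (adjusted p = 0.0175) in the edgeR test, and PN-20/PT12 passed without herd 6 lesion 5 (adjusted p = 0.0382). In simulated data this test called many unchanged taxa, so these calls carry little weight.

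Of the taxon groups fixed beforehand, taxa known by a code or clone alone made up the largest share, 31.1% ± 17.4 (SD, n = 36), from 26 taxa. The preset group for another genus or no classification followed with 25.3% ± 7.69 (SD, n = 36). It was almost wholly made up of clusters without a name, which alone held 25.2%, so it does not measure reads of another genus. The group of T. pedis, T. putidum and T. denticola made up 18.4% ± 15.8 (SD, n = 36), that of T. phagedenis 14.6% ± 9.75 (SD, n = 36) and that of T. medium and T. vincentii 9.92% ± 12.6 (SD, n = 36). T. refringens, the named member of its group, had 0.630% ± 1.45 (SD, n = 36) and was named in 10 lesions. No cluster was named after the other oral species or the gut and rumen species of the lists. None of the 6 groups with reads differed between herds in the permutation Kruskal-Wallis test adjusted over the list alone, the lowest being the T. pedis group (p = 0.0176, adjusted p = 0.106). Without herd 3 lesion 1, and likewise without herd 7 lesion 6, 1 group passed.

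After thinning to 286 reads a lesion held 8.62 ± 2.46 named taxa (SD, n = 36). The Shannon index, taken without thinning from the shares of named reads, was 1.59 ± 0.319 (SD, n = 36). Neither measure differed detectably between herds (permutation Kruskal-Wallis p = 0.659 and p = 0.887, adjusted p = 0.887 for both). Thinning was done after clusters were named and hardly removes a named taxon, so the comparison of taxa is not free of depth. In herd 6 lesion 2, with 7235 reads, it took 12 named taxa to 10.89. Total reads did differ between herds (permutation p = 0.00198), and before thinning the number of named taxa rose with log10 total reads (Pearson r = 0.518, permutation p = 0.00118, Spearman rho = 0.428, permutation p = 0.00968, n = 36). Without the 2 lesions farthest from the median depth these were r = 0.403 (permutation p = 0.0180) and rho = 0.327 (permutation p = 0.0595). Among the 25 lesions with fewer named clusters r was 0.572 (permutation p = 0.0034, rho = 0.510, permutation p = 0.0104), and without the 2 farthest in depth rho no longer passed (r = 0.446, permutation p = 0.0341, rho = 0.378, permutation p = 0.0759). Among the 11 lesions with fully named larger clusters r was 0.588 (permutation p = 0.0541, rho = 0.566, permutation p = 0.0730), which rested on the 2 lesions farthest in depth (r = 0.0896 without them). Within herd 7 the correlation was r = 0.749 (exact permutation p = 0.0264, rho = 0.740, p = 0.0429, n = 8), which was lost without its 2 lesions farthest in depth (r = 0.617, exact permutation p = 0.194, rho = 0.638, p = 0.2). Within herd 6 it was r = 0.520 (exact permutation p = 0.30, rho = 0.617, p = 0.233, n = 6). Without the 2 lesions of herd 6 farthest in depth it was higher but did not pass (r = 0.762, exact permutation p = 0.333, rho = 0.894, p = 0.333).

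Herd means were compared with the sampling date, in a family of 8 measures over 10 herds. T. medium/PT5 had larger shares in herds sampled later (r = 0.697, permutation p = 0.0266, rho = 0.661, permutation p = 0.0435), and so did PT8 by rank (r = 0.528, permutation p = 0.0974, rho = 0.705, permutation p = 0.0276), but neither passed the adjustment (lowest adjusted p = 0.144). Without herds 2 and 3, the 2 farthest from the median date, T. medium/PT5 had r = 0.729 (exact permutation p = 0.0421, adjusted p = 0.168) and rho = 0.833 (p = 0.0154, adjusted p = 0.0742). Without these herds PT8 had r = 0.471 (exact permutation p = 0.234) and rho = 0.571 (p = 0.151), so not even its unadjusted rank p was under 0.05 over the 8 herds left. T. pedis had r = -0.455 (permutation p = 0.187) and rho = -0.423 (permutation p = 0.224) over all 10 herds, but without herds 2 and 3 it had r = -0.807 (exact permutation p = 0.00193, adjusted p = 0.0155) and rho = -0.814 (p = 0.0186, adjusted p = 0.0742). The relation of T. medium/PT5 to date did not hold in both naming batches, each with lesions of 6 herds. It had r = 0.847 (exact permutation p = 0.0444, rho = 0.486, p = 0.356) among lesions with fully named larger clusters and r = -0.0976 (exact permutation p = 0.864, rho = -0.0857, p = 0.919) among the others. In the same order PT8 had r = -0.0713 (exact permutation p = 0.892, rho = -0.152, p = 0.833) and r = 0.359 (p = 0.578, rho = 0.257, p = 0.658), and T. pedis had r = -0.262 (exact permutation p = 0.65, rho = -0.213, p = 0.733) and r = -0.659 (p = 0.156, rho = -0.551, p = 0.272). Among the other measures with an unadjusted p under 0.05, T. phagedenis had r = -0.920 (exact permutation p = 0.0153, adjusted p = 0.122, rho = -0.829, p = 0.0583) among lesions with fewer named clusters, against r = 0.0338 (permutation p = 0.929) over all 10 herds. The Shannon index had r = -0.817 (exact permutation p = 0.0472, adjusted p = 0.189, rho = -0.829, p = 0.0583) among those with fully named larger clusters. No measure passed the adjustment within a batch. Without the 2 herds farthest in date, the r of 0.847 for T. medium/PT5 was 0.506 (exact permutation p = 0.667, rho = 0.2). Herd 11 entered that batch with lesion 2 only, which held 53.5% T. medium/PT5 in 286 reads.

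Co-occurrence showed 2 sets of treponemes that were named in the same lesions. The first set was PN-20/PT12, PT1 and PT15. All 8 lesions with PT1 were among the 10 lesions with PN-20/PT12, where 2.22 were expected (Fisher's exact test, adjusted p = 0.000116). PT15 was named with PT1 in 7 lesions (1.78 expected, adjusted p = 0.00029) and with PN-20/PT12 in 7 (2.22 expected, adjusted p = 0.00204). PT4 was named in all 10 lesions with PN-20/PT12 (6.11 expected, adjusted p = 0.0265).

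The second set, T. pedis, PT16 and PT18, was less firm, since PT18 with T. pedis was lost in 22 of 36 omissions of a single lesion, and neither pair with T. pedis passed with presence permuted within herds. PT16 was named with T. pedis in 10 lesions (4.89 expected, Fisher's exact test, adjusted p = 0.00427) and with PT18 in 9 (4.58 expected, adjusted p = 0.0265), and PT18 with T. pedis in 11 (6.67 expected, adjusted p = 0.0431). A table gave T. pedis and PT16 together as the name of a cluster, so reads of these taxa may not be fully separated. The clone 18f-22 was named with oral taxon 517 in 13 lesions (7 expected, adjusted p = 0.00204) and with PT18 in 12 (7.5 expected, adjusted p = 0.0431), and 9T-42 with PT8 in 7 (3.11 expected, adjusted p = 0.0265). PT18 and PT4 were the only called pair found together less often than expected, in 5 lesions against 9.17 (adjusted p = 0.0431), and at 1% of reads in 1 lesion against 7.08. With any named cluster counted as presence this call was lost in 27 of 36 omissions of a single lesion. Without herd 10 lesion 3 the pairs called apart numbered 4.

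**Figure D3:**
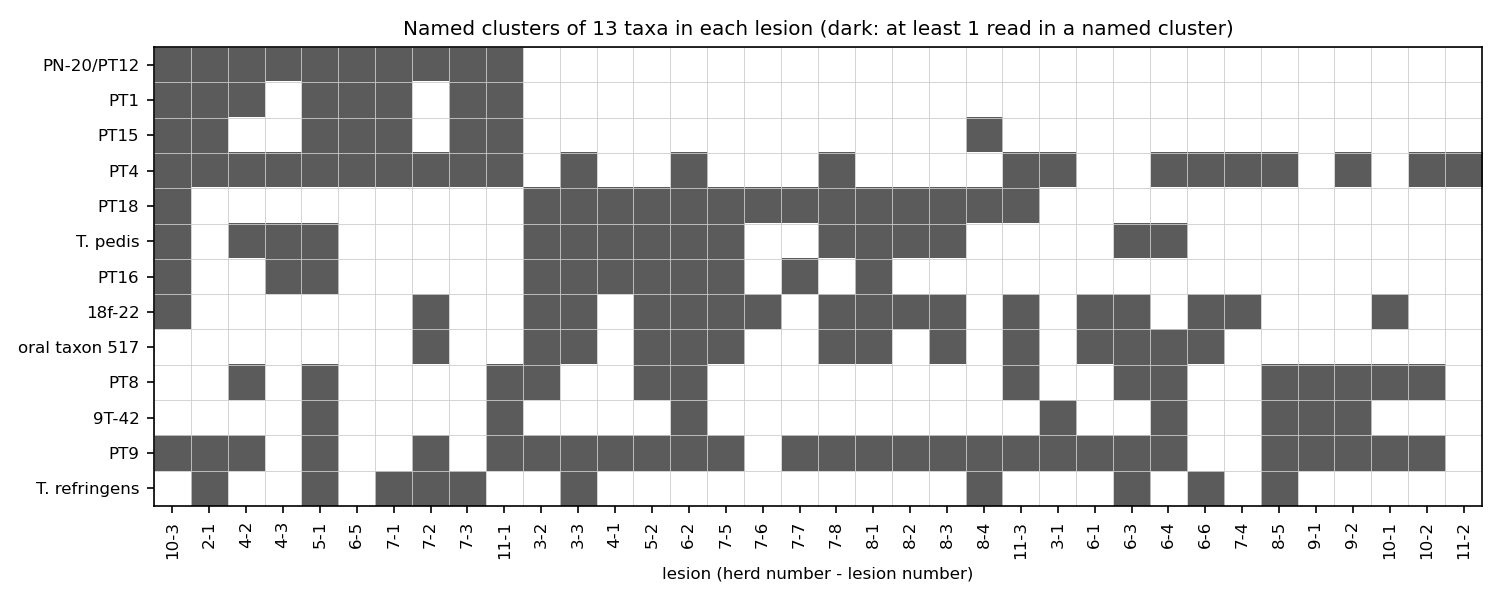
Rows are the 13 taxa tested for co-occurrence and columns the 36 lesions, ordered by whether PN-20/PT12 and then PT18 was named. Dark squares mark taxa with a named cluster, and no named cluster held under 10 reads. The 8 lesions with PT1 all lie among the 10 lesions with PN-20/PT12.

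In all, 11 of 78 pairs of the 13 taxa passed, and all 11 also passed with presence permuted within naming batches. When each of the 36 lesions was left out in turn, 5 pairs passed every time, namely PN-20/PT12 with PT1, PN-20/PT12 with PT15, PT1 with PT15, 18f-22 with oral taxon 517 and PT16 with T. pedis. PT16 with PT18 passed in 32 omissions, 9T-42 with PT8 in 33, PN-20/PT12 with PT4 in 29, 18f-22 with PT18 in 20, PT18 with T. pedis in 14 and PT18 apart from PT4 in 9. With presence permuted within herds 5 of them passed, namely PN-20/PT12 with PT1, PN-20/PT12 with PT15, PT1 with PT15, 18f-22 with oral taxon 517 and PT16 with PT18. At a presence limit of 1% of reads, which left 9 taxa to test, 3 passed, namely PT16 with T. pedis, PT16 with PT18, and PT18 apart from PT4. There PT1, PT15 and 9T-42 were in under 20% of lesions. The pairs among PN-20/PT12, PT1 and PT15, and 9T-42 with PT8, were therefore not tested at this limit. At 1% PN-20/PT12 and PT1 were together in 6 lesions, against 1.75 expected.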

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

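The outlying lesions were sought by a rule fixed before the data were examined. All tests of explanations in this part were chosen after the result, or part of it, was seen.

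Within herds 6, 7 and 8, 13 of 40 values tested had 1 lesion far from the rest by Dixon's test. Its rate of about 1 in 20, or about 2 values, assumes normally distributed values. That rate is no guide for shares with many zeros. Many of these taxa were named in few lesions, so a single lesion with the taxon stands apart easily. In herd 6, lesion 2 held 28.8% T. pedis (next highest 0.669%) and 3.93% PT18, and lesion 5 held 33.7% PT15 and 5.04% PN-20/PT12. In herd 7, lesion 5 held 15.6% T. pedis, lesion 7 held 35.4% PT18, lesion 2 held 22.2% PT4, lesion 3 held 1.20% PT15, and lesion 6 held 3.29% of the clone 18f-22. In herd 8, lesion 1 held 12.1% T. pedis, lesion 5 held 48.2% PT8 and 1.73% PT4, and lesion 4 held 0.651% PT15. The largest cluster without a name had 97 reads, in herd 6 lesion 5.

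PN-20/PT12 and PT1 were named together in 8 lesions of 7 herds, and PT1 was never named without PN-20/PT12. After thinning to 286 reads the median Fisher p over 100 draws was 1.49e-06, the same as without thinning. Thinning was done after clusters were named and hardly removes a named taxon, so it cannot decide whether unequal depth plays a part. A single organism giving both names in a fixed proportion is argued against by the ratio of PT1 to PN-20/PT12 reads. The highest ratio was 46.0 times the lowest over the 8 lesions. Uneven use of both names between lesions would also vary this ratio, so it cannot decide that case. A shared herd alone is argued against by permutation within herds (adjusted p = 0.0234). That these treponemes may share a niche within lesions stays open as a hypothesis, beside carry-over between amplicons, which was not tested.

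T. pedis had its highest shares in herds 3, 4 and 5, all with fully named larger clusters. If every unnamed cluster of 12 or more reads were T. pedis, the highest mean of another herd would be 14.4%, still below the 25.4% of herd 3, and the unadjusted permutation p would be 0.0560 in place of 0.00612 (adjusted p = 0.141, so no call was lost). Naming alone did not raise another herd to that level, but its part in the difference cannot be told apart from herd, because the naming batches nearly coincide with herds. A trend with sampling date cannot be told apart from herd (Spearman rho = -0.423, n = 10, permutation p = 0.224), since each herd had 1 date. Without herds 2 and 3 the correlation was stronger (r = -0.807, exact permutation adjusted p = 0.0155, rho = -0.814, adjusted p = 0.0742). A difference between herds in the bacteria themselves also stays open.

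Named clusters with under 97% identity to their best match numbered 103 in 23 lesions and held 6.37% of named reads. Of these, 90 lay beside a cluster of their taxon at 97% or more, and 1.11% of the 90 (1 cluster of T. denticola/PT7 with 82 reads, in herd 5 lesion 1) was larger than every such cluster in its lesion. The other 13 had none beside them, among them canine oral taxon 198 (85 reads in herd 6 lesion 6) and 9T-42 (57 reads in herd 6 lesion 2), so their size cannot be compared. Sequencing error and related organisms therefore cannot be told apart, because a single cluster decides nothing and the tables hold no sequences. Chimeras between taxa were not tested.

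With 0 taxa called between herds by edgeR, all 100 splits of the lesions give at least as many by construction, so their count tests nothing. The other splits called a median of 0 and at most 12 taxa. The test also called 26.5% of unchanged taxa in simulated counts with the same dispersions, and whether the split with 12 reflects a structure of the samples was not tested.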

How the results depend on the processing

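Alternatives using shares of named reads, unmerged names, 97% identity, naming batches (for dates and depth too), communities without T. pedis or a 5% presence limit were chosen after the data were seen. No paired analysis was possible because lesion numbers follow the order of deposition. The cause of a change was not tested unless stated.

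The 6 leading taxa made up 73.5% of named reads, since the denominator is smaller. For the rank order, 3 pairs passed on the log scale. The herd share of the community (0.339) was 0.297 for square roots, 0.259 for Jaccard distances, 0.270 for centred log ratios, 0.263 for herds with at least 3 lesions, 0.277 without T. pedis, and 0.137 and 0.254 within the naming batches, none past the threshold. It passed for shares of named reads, 97% identity and unmerged names, and without each lesion in turn. The shares for herds with at least 3 lesions and within the naming batches come from fewer herds, so their size cannot be set against 0.339. The within-herd difference in distance (-0.0494) was -0.0254 for square roots, -0.0107 for Jaccard distances, -0.00987 among lesions with fewer named clusters, and turned to 0.0837 among those with fully named ones. It lay between -0.0576 and -0.0400 without single lesions, with p from 0.0142 to 0.0899, and missed the threshold without 14 of the 35, namely herd 3 lesion 3, herd 4 lesions 2 and 3, herd 5 lesion 1, herd 6 lesions 1, 3 and 6, herd 7 lesion 8, herd 8 lesions 1, 2, 3 and 4, and herd 9 lesions 1 and 2. Taxa called between herds numbered 5 without a filter and 0 to 2 without single lesions (2 without herd 6 lesion 5, and 1 without herd 4 lesion 2 or herd 8 lesion 5). Co-occurring pairs (11) numbered 3 at 1% of reads, all among the 11, 1 at 5%, which was none of the 11, 5 within herds, all among the 11, 7 with unmerged names, of which 5 were among the 11, and 6 to 13 without single lesions. They numbered 6 without herd 3 lesion 2, herd 5 lesion 2, herd 7 lesion 5, herd 8 lesion 1 or herd 11 lesion 1, and 7 without herd 8 lesion 2, 3 or 5 or herd 9 lesion 2. The limits of 1% and 5% left 9 and 7 taxa to test, so part of the 11 pairs had no test there. At 5% only PT18 with T. pedis and PT18 with PT4 of the 11 were tested. Preset groups called numbered 0 to 1 without single lesions (1 without herd 3 lesion 1 or herd 7 lesion 6). Leaving out single lesions moved the leading taxa between 54.3% and 56.5%. No richness measure, and no date measure by rank, passed the adjusted threshold under the alternatives run. By Pearson correlation with date T. pedis passed without herds 2 and 3 (adjusted p = 0.0155), and T. medium/PT5 had r = -0.0976 among lesions with fewer named clusters. The relation of depth to named taxa (rho = 0.428) was 0.566 in the 11 lesions with fully named larger clusters (permutation p = 0.0730), which missed the threshold, and 0.202 there without the 2 lesions farthest in depth. It passed in the other 25. A presence limit of 0.1% of reads changed neither it, nor the count of co-occurring pairs, nor the lesions counted per named taxon, and so tests nothing. Among single taxa and pairs, 300 of the other alternatives kept their side, 10 weakened, 3 strengthened and 10 moved. Depth limits the rare taxa, since lesions had as few as 286 reads.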

Other observations

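The counts in this part were made after the lesions with PN-20/PT12 were seen. PT2, PT13 and PT3, further coded taxa, were named only in lesions with PN-20/PT12. PT2 was named in 5, PT13 in 4 and PT3 in 3 of its 10 lesions, and in 0 of the 26 others. In herd 7 lesion 3, where PN-20/PT12 held 46.8%, PT1 held 6.77%, PT13 held 3.54%, PT2 held 2.03% and PT3 held 2.03% of reads. In herd 6 lesion 5, where PT15 held 33.7%, PN-20/PT12 held 5.04% and PT4 held 9.30%. A table gave PT3 and PT12 together as a cluster's name, so these 2 are not fully separated. Oral taxon 517 was named in none of the 8 lesions with PT1, where 3.11 were expected (Fisher's exact test, adjusted p = 0.0684).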
